A study of Ovis aries with 6 samples.

How the data were processed

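RNA sequencing libraries of 6 sheep samples, 3 with MEOX2 overexpression and 3 labelled NC, were analysed from 1 table of FPKM values deposited by the authors. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA Library Prep Kit. CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used, per the submitters' processing notes, which give no roles or settings here. The genome build, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart, and coordinates are those of the deposited table. Column names carried the prefix pHBLV and the group and replicate number, which matched each column to 1 sample.

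The table held 26425 rows, 25197 with Ensembl identifiers and 1228 with other identifiers; 18262 had a symbol, and 23 symbols had been turned into spreadsheet dates. The authors' FPKM values, multiplied by the gene length in the table, were whole multiples of 1 step per library for 100% of values above 0 (tolerance 0.001 of a read). The reads recovered this way totalled 11772772 to 12230863 per library. The library size implied by the FPKM values was 0.967 to 1.02 times that total and equalled the median-of-ratios size factor times the geometric mean of the totals, so the deposited FPKM values were already scaled by size factors. The 10 genes with most reads took 16.5% to 18.2% of reads and mitochondrial genes 0.796% to 1.27%. Rows of different length but equal FPKM rest on different read numbers, and short or low genes are the least precise.

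Log2(FPKM + 1) values of the 13121 genes with a mean of at least 1 FPKM over the 6 samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, MEOX2 against NC, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change on this scale understates the change of low genes. Values are group means ± SD of FPKM. Fixed lists, 24 in all, were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over the 21 lists with at least 3 tested members; 3 marker lists had fewer. List symbols were matched to the table by symbol (565), by synonyms in the RefSeq gene table of assembly ARS-UI_Ramb_v3.0 (11) or by hand to a former symbol (3), and 74 were not matched. The camera form with an estimated correlation uses only the few residual degrees of freedom of 6 samples, so it has less power. The MEOX2 level was also tested with an exact permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

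The groups, tests, lists and the alternatives described as planned were fixed before the data were examined. So was the rule for named genes: MEOX2; of called genes with a symbol and no overlap between groups, the 10 largest rises and the 10 largest falls; up to 4 members of each list with the smallest p; and a fixed set of adipogenic, PI3K/AKT and cell cycle genes where measured. Some genes that the rule names are not reported here. Genes outside that rule are said to be chosen after their values were seen. Alternatives were other pseudocounts, filters, scalings, variance models, a replicate block, each library left out in turn and other list tests. A fit with limma voom on the recovered reads and one on protein-coding rows alone were added after seeing the data.

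Libraries of one group differed by 3.75 to 12.4 in chi-square per gene, where sampling noise alone gives about 1 per gene. No library was therefore a mere resequencing of another, but whether any were made from the same RNA cannot be told from this. The first principal component (34.0% of variance) separated the groups, and NC sample 3 stood apart from the other libraries on the second (22.2%). The fit was tested on simulated reads for this comparison (13111 genes run, n = 3 per group): limma called 85.6% of 97 genes changed 2.0-fold and 58.2% of 98 genes changed 1.5-fold, with 12 false calls among 152. All simulated genes had the same dispersion, 0.00615, and no simulated library stood apart. Real genes that vary more are harder to call, so these shares may be too high for the real data.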

Results

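RNA sequencing was performed on sheep cells from the stromal vascular fraction of adipose tissue, the mixed cell fraction that contains adipocyte precursors. The sample labels give the cell type as adipocyte. Of 6 samples, 3 carried forced expression of MEOX2, a mesodermal homeobox transcription factor, and 3 formed the control group labelled NC. The values were FPKM, read counts scaled to gene length and library size. Whole reads per gene recovered from these values totalled 11772772, 12230863 and 12013153 in MEOX2 samples 1 to 3 and 11883558, 12215324 and 12146611 in NC samples 1 to 3. Between 16426 and 16623 genes had a value above 0 in each library.

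The series asks how MEOX2 affects adipogenic differentiation and whether PI3K/AKT signalling is involved. MEOX2 itself (ENSOARG00000008280, chromosome 4, 24100798 to 24175729, minus strand; genome build not given in the sources used here) reached 132.9 ± 23.0 FPKM (SD, n = 3) in the overexpressing samples and 9.98 ± 0.910 FPKM (SD, n = 3) in NC, a 13.3-fold difference. The change on the log2(FPKM + 1) scale was 3.60 (SE 0.13), with a limma adjusted p of 1.15e-05. The 3 overexpressing libraries lay between 107.7 and 152.7 FPKM and the 3 NC libraries between 9.03 and 10.8 FPKM. An exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest value that 3 against 3 samples allow. Gene-level reads did not separate the introduced MEOX2 from the endogenous gene.

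Of 15 mature adipocyte markers, 6 were lower in cells overexpressing MEOX2 and 9 were not called. The list as a whole was lower by camera of limma (adjusted p = 3.53e-10), and that call was lost with an estimated correlation (adjusted p = 0.155 with an estimated correlation). By fry the list was lower (adjusted p = 0.00482). ADIPOQ, the adipokine adiponectin (chromosome 1, 198618705 to 198631249), fell 5.18-fold, from 36.9 ± 2.67 FPKM in NC to 7.13 ± 1.08 FPKM (SD, n = 3 each), and FABP4, the fatty acid carrier of fat cells (chromosome 9, 57536525 to 57541042), fell 2.96-fold, from 235.3 ± 26.3 to 79.6 ± 9.72 FPKM (SD, n = 3 each). PPARG, the central transcription factor of adipogenesis and listed as PPARG2 (chromosome 19, 56552358 to 56652679), fell from 13.7 ± 0.458 to 8.09 ± 0.760 FPKM. Genes with higher levels included PLAC8, FOXO4, SFRP1 and CTGF. None of 31 transcripts of the PI3K/AKT core pathway was called by limma, against 1 by limma voom and 3 at an unadjusted p under 0.05. Transcript levels do not measure phosphorylation or activity of the pathway, so whether its signalling changed stays open.

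Of 13121 genes tested with limma, 350 passed an adjusted p of 0.05, 198 higher and 152 lower with MEOX2. Of these, 64 changed by at least 1 on the log2 scale, 34 higher and 30 lower. The 3 values of each group did not overlap for 2483 genes (18.9%), against 10% by chance. Leaving out single libraries lowered the count of 350 to between 117, without NC sample 1, and 276, without NC sample 3; it was 188, 195 and 130 without MEOX2 samples 1, 2 and 3 and 180 without NC sample 2. With each library left out in turn, 98 of the 350 genes, 57 higher and 41 lower, passed every time. Such fits have fewer samples and less power, so a call lost in one need not rest on the library left out. The p-values here measure only the spread between these samples, which may be technical.

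**Figure D1:**
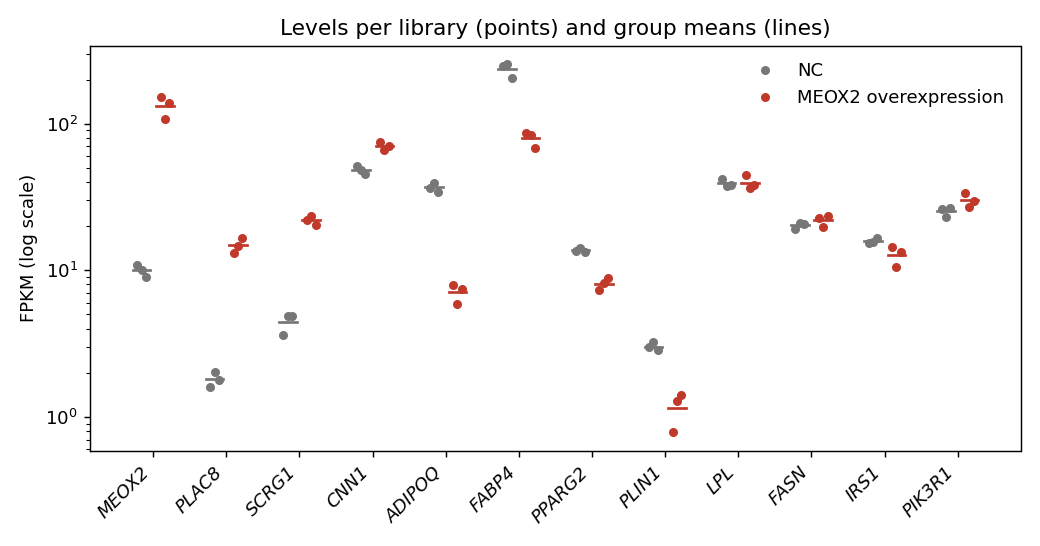
FPKM (log axis) of 12 genes in each library, with NC in grey and MEOX2 overexpression in red; points are libraries and lines are group means (n = 3 each). MEOX2, PLAC8, SCRG1 and CNN1 were higher and ADIPOQ, FABP4, PPARG2 and PLIN1 lower with MEOX2, while the changes of LPL, FASN, IRS1 and PIK3R1 did not pass an adjusted p of 0.05.

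Among the largest rises, PLAC8 (chromosome 6, 97495356 to 97504161) went from 1.81 ± 0.210 to 14.8 ± 1.799 FPKM (SD, n = 3 each), a log2 change of 2.49 with a limma adjusted p of 4.79e-05. SCRG1, a secreted protein linked to mesenchymal stem cells, rose by 2.08 and CNGA3, a cyclic nucleotide-gated channel subunit, by 2.02. FOXO4, a forkhead factor regulated by AKT phosphorylation (chromosome X, 60400592 to 60405719), rose from 13.9 ± 0.682 to 42.6 ± 2.31 FPKM, by 1.54 on the log2 scale. SMOC2, XPNPEP2, DPYSL3 and RFTN1 rose by 1.38, 1.37, 1.34 and 1.33, each with at least 95 reads in every library. PPP1R14A, an inhibitor of myosin phosphatase, rose by 1.33, and its call was lost without any one of 3 of the 6 libraries (limma adjusted p up to 0.0657). The rise of SNORD14, a small nucleolar RNA, by 1.47 rested on 0 to 3 reads per library and was lost in 5 of the 6 fits with a library left out, with limma adjusted p values up to 0.118.

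Among the largest falls, complement component C7 went from 10.5 ± 0.548 to 2.21 ± 0.154 FPKM, by -1.84 on the log2 scale with a limma adjusted p of 8.43e-05. H19_1, a row of 70 bases at the imprinted H19 RNA, fell from 188.7 ± 76.8 to 38.4 ± 12.4 FPKM and varied widely among NC samples. The log2 change of H19_1, -2.21, lost its call without a filter on low genes (limma adjusted p = 0.059996) and with a robust fit (0.0548). A row named 7SK (ENSOARG00000023715) fell by 1.82, and because 7SK RNA has many near-identical copies its reads are uncertain. ASGR2 and its neighbour ASGR1, the asialoglycoprotein receptor subunits, fell by 1.32 and 1.26. ASGR1 lost its call without NC sample 1 or NC sample 2 (limma adjusted p up to 0.0549). S100A12, CCL20 and AVPR1A, a vasopressin receptor, fell by 1.43, 1.37 and 1.16.

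Adjusted over the list alone, 9 of the 15 mature adipocyte markers fell and none rose. The 6 that fell over all genes were ADIPOQ, FABP4, PLIN1, CIDEC, FABP5 and TUSC5, the last pair chosen after their values were seen. FABP5 and TUSC5 each lost their call in 5 of the 6 fits with a library left out (limma adjusted p up to 0.156 and 0.148). PLIN1 and CIDEC, proteins of the lipid droplet coat, fell from 3.02 ± 0.198 to 1.16 ± 0.329 FPKM and from 2.86 ± 0.145 to 1.30 ± 0.144 FPKM (SD, n = 3 each). Leaving out any single library ended the calls of PLIN1 (limma adjusted p from 0.0514 to 0.0872) and CIDEC (0.0554 to 0.0958), whereas ADIPOQ and FABP4 passed in all 6 such fits. LPL, which releases fatty acids from lipoproteins, was at 39.7 ± 4.28 FPKM with MEOX2 and 39.5 ± 2.45 FPKM in NC. The median log2 change of the list was -0.57.

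Of 13 adipogenic transcription factors, PPARG2 fell (log2 change -0.69, limma adjusted p = 0.00875) and 12 were not called; adjusted over the list alone, 2 fell. CEBPA was at 1.797 ± 1.26 FPKM with MEOX2 and 5.28 ± 3.21 FPKM in NC, with a limma adjusted p of 0.377, and CEBPB was at 30.1 ± 3.65 and 35.1 ± 6.45 FPKM. The adipogenic transcription factors list was not called (camera of limma, adjusted p = 0.1003), except without MEOX2 sample 3 (0.0430). Of 22 genes of fatty acid and triglyceride synthesis, FADS1 (0.49) and ACSL3 (0.41) rose and 20 were not called, FASN among them at 21.9 ± 2.03 against 20.2 ± 0.947 FPKM; adjusted over the list alone, 3 rose and 1 fell. FADS1 and ACSL3 each lost their call in 5 of the 6 fits with a library left out (limma adjusted p up to 0.107 and 0.161). That list was not called (camera of limma, adjusted p = 0.636), and its median of 0.03 and mean of -0.02 differed in sign. None of 18 genes of lipolysis and fatty acid oxidation was called by limma, against 3 by limma voom and 6 at an unadjusted p under 0.05; 4 were lower when adjusted over the list alone, and CPT1A, PNPLA2, HSL and G0S2 had the smallest p. The lipolysis and fatty acid oxidation list was lower (camera of limma, adjusted p = 0.0176; adjusted p = 0.171 with an estimated correlation) and lost its call without NC sample 2 (0.0512).

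None of 31 genes of PI3K/AKT core signalling was called by limma over all genes, and none was when adjusted over the list alone. IRS1 was at 12.8 ± 1.97 FPKM with MEOX2 and 15.9 ± 0.622 FPKM in NC (limma adjusted p = 0.282). PIK3R1 and AKT2 had log2 changes of 0.24 and 0.28, with SEs of 0.10 and 0.14. The list was not called (camera of limma, adjusted p = 0.950), and its median of -0.01 and its mean and test differed in sign. AKT1 was not analysed here. Activity of the pathway was not measured. Among 28 growth factors and receptors upstream of PI3K/AKT, FGF7 (-0.66), FGF-10 (-0.56) and C-MET (-0.68) fell, 25 were not called, and 4 fell when adjusted over the list alone. FGF-10 lost its call without MEOX2 sample 3 or NC sample 1, and C-MET without any one of the 6 libraries (limma adjusted p up to 0.0752 and 0.126). The growth factors and receptors upstream of PI3K/AKT list was lower (camera of limma, adjusted p = 0.0160; adjusted p = 0.419 with an estimated correlation). It lost its call without MEOX2 sample 2 (0.117) or NC sample 3 (0.0573).

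**Figure D2:**
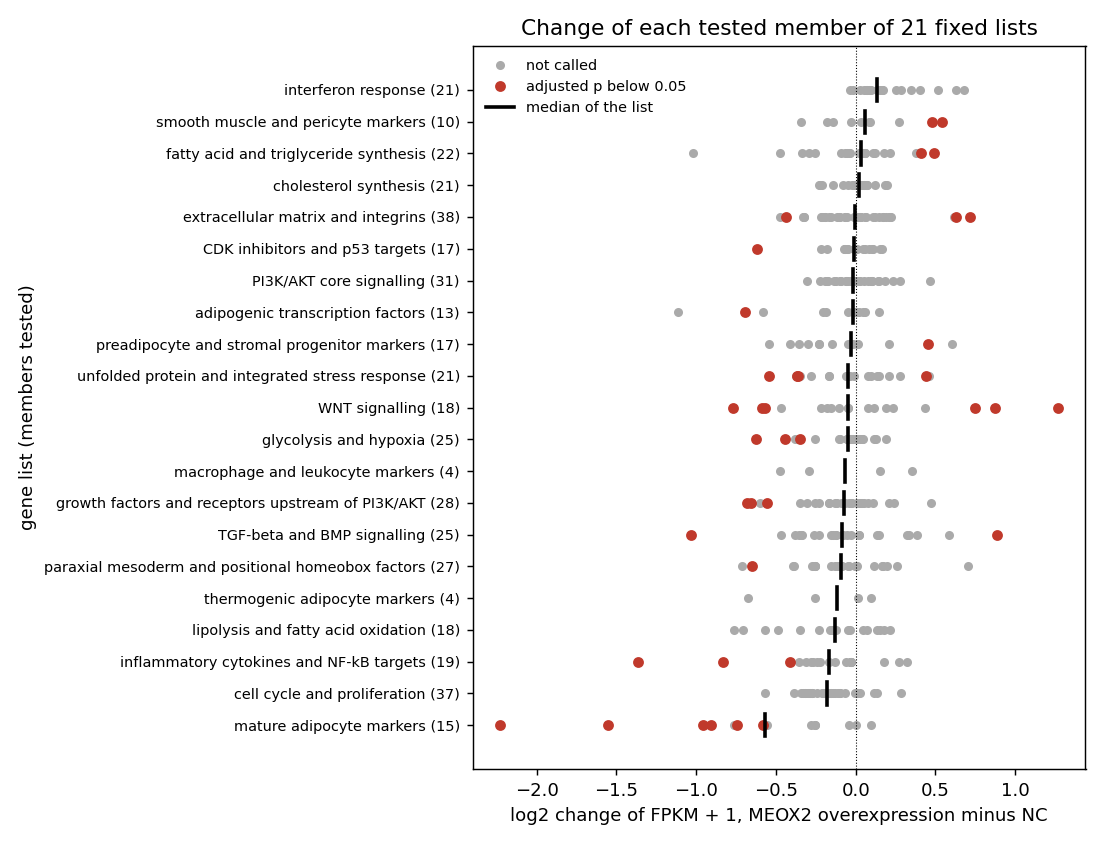
Log2 change of FPKM + 1 (MEOX2 overexpression minus NC, horizontal axis) of each tested member of 21 gene lists (vertical axis, members tested in brackets); red points passed a limma adjusted p of 0.05, grey points did not, and black bars are medians. The mature adipocyte markers had the lowest median, -0.57, and the interferon response list the highest, 0.13.

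WNT pathway genes moved both ways. SFRP1, a secreted WNT antagonist, rose from 31.6 ± 2.46 to 78.2 ± 14.6 FPKM (log2 change 1.27, limma adjusted p = 0.00253), and DKK3 rose by 0.75. The receptor FZD4 fell by 0.77 and SFRP2 by 0.59. FZD7 and SFRP4, chosen after their values were seen, rose by 0.87 and fell by 0.57; FZD7 lost its call without any one of the 6 libraries (limma adjusted p up to 0.0833) and SFRP4 in 2 of these fits (0.0776). Of the 18 members tested, 3 rose, 3 fell and 12 were not called; adjusted over the list alone, 3 rose and 4 fell. The list test gave an adjusted p of 0.950 by camera of limma, with a median of -0.05 and a mean of 0.04. In TGF-beta and BMP signalling, CTGF, a matricellular protein induced by TGF-beta, rose from 140.2 ± 5.85 to 260.1 ± 10.1 FPKM, and ID1, a BMP target, fell from 117.6 ± 15.6 to 56.9 ± 6.30 FPKM (SD, n = 3 each). The other 23 of its 25 members were not called, 3 rose and 6 fell when adjusted over the list alone, and the list was not called (camera of limma, adjusted p = 0.288).

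Of 38 genes of the extracellular matrix and integrins, THBS1 (0.63) and COL12A1 (0.72) rose, BGN fell by 0.43 and 35 were not called; adjusted over the list alone, 2 rose and 5 fell (camera of limma for the list, adjusted p = 0.950; the median was -0.00485 and the mean 0.00474). COL12A1 and BGN each lost their call in 4 of the 6 fits with a library left out, with limma adjusted p values up to 0.103 and 0.0776. Of 10 smooth muscle and pericyte markers, CNN1 rose from 48.4 ± 3.09 to 71.0 ± 4.53 FPKM and CSPG4 from 14.5 ± 0.352 to 20.7 ± 2.01 FPKM, 8 were not called, and 3 rose when adjusted over the list alone (camera of limma for the list, adjusted p = 0.213). CNN1 lost its call without MEOX2 sample 3 and CSPG4 without any one of the 6 libraries (limma adjusted p up to 0.0615 and 0.133). Of 17 preadipocyte and stromal progenitor markers, F3 rose by 0.45, losing its call without any one library (limma adjusted p up to 0.175). The other 16 were not called, 1 rose and 3 fell when adjusted over the list alone, and the list was not called (camera of limma, adjusted p = 0.257).

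None of 37 cell cycle genes was called by limma, over all genes or adjusted over the list alone, nor by limma voom, while 11 had an unadjusted p under 0.05. Of the 37, 31 had a negative log2 change, and CCNA2, PCNA, KIF20A and RRM2 had the smallest p, with log2 changes of -0.32, -0.27, -0.28 and -0.24. The list was lower, with a median of -0.18 (camera of limma, adjusted p = 9.05e-06). That call was lost with an estimated correlation (adjusted p = 0.0959 with an estimated correlation), while the list was also lower by fry (adjusted p = 0.00125). Of 17 CDK inhibitors and p53 targets, CDKN2C fell by 0.62 and 16 were not called, with 1 lower when adjusted over the list alone (camera of limma, adjusted p = 0.895). CDKN2C lost its call in 5 of the 6 fits with a library left out (limma adjusted p up to 0.131). CDKN1A was at 407.5 ± 22.1 and 367.4 ± 32.8 FPKM in MEOX2 and NC samples.

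Of 19 inflammatory cytokines and NF-kB targets, the chemokines CCL20 (149.8 ± 8.97 to 57.5 ± 3.41 FPKM) and IL8 (116.7 ± 6.999 to 65.3 ± 6.78 FPKM) and the mitochondrial enzyme SOD2 (-0.41) fell, and 16 were not called; adjusted over the list alone, 4 fell and 1 rose. SOD2 lost its call in 5 of the 6 fits with a library left out (limma adjusted p up to 0.126). The list was lower (camera of limma, adjusted p = 0.00129; adjusted p = 0.155 with an estimated correlation). None of 21 interferon response genes was called by limma, against 3 by limma voom and 6 at an unadjusted p under 0.05; 4 were higher when adjusted over the list alone, IFIT3, IFI6, MX1 and OAS2 having the smallest p. That list was higher (median 0.13; camera of limma, adjusted p = 5.75e-04; adjusted p = 0.155 with an estimated correlation). Of 25 genes of glycolysis and hypoxia, PFKFB3, SLC2A1 and ADM fell by 0.44, 0.35 and 0.63, and 22 were not called; adjusted over the list alone, 6 fell. SLC2A1 and ADM lost their calls without any one of the 6 libraries and PFKFB3 in 4 of these fits (limma adjusted p up to 0.148, 0.182 and 0.146). The glycolysis and hypoxia list was lower (camera of limma, adjusted p = 0.0123; adjusted p = 0.457 with an estimated correlation) and lost its call without NC sample 1 (0.0560) or NC sample 2 (0.114).

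Of 21 genes of the unfolded protein and integrated stress response, the serine synthesis enzyme PSAT1 rose by 0.44, the endoplasmic reticulum proteins PDIA4, HSP90B1 and CRELD2 fell by 0.36, 0.37 and 0.55, and 17 were not called; adjusted over the list alone, 3 rose and 6 fell (camera of limma, adjusted p = 0.336). Each of these 4 lost its call in 5 or 6 of the fits with a library left out (limma adjusted p up to 0.179). Of 27 positional homeobox and paraxial mesoderm factors, SIX2 fell by 0.65, losing its call in 4 of the 6 fits with a library left out (limma adjusted p up to 0.102). The other 26 were not called, 1 was lower when adjusted over the list alone, and the paraxial mesoderm and positional homeobox factors list was not called (camera of limma, adjusted p = 0.1003) except without MEOX2 sample 3 (0.0417). MEOX1, the paralog of MEOX2, was at 3.67 ± 0.344 and 4.67 ± 0.731 FPKM in MEOX2 and NC samples and was not called. None of 21 genes of cholesterol synthesis was called by limma, over all genes or adjusted over the list alone, nor by limma voom, while 3 had an unadjusted p under 0.05, and the list was not called (camera of limma, adjusted p = 0.990; median 0.02, mean -0.00323).

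Of 20 macrophage and leukocyte markers, 4 were tested (CD14, CD68, CD163 and LAPTM5) and none was called by limma, against 1 by limma voom and 1 at an unadjusted p under 0.05, with 1 lower when adjusted over the list alone (camera of limma, adjusted p = 0.895). CD14 was at 117.0 ± 7.01 FPKM with MEOX2 and 105.2 ± 4.42 FPKM in NC. Of the 20 markers, 16 did not pass the filter, 8 had under 5 reads in every library and 5 of these had 0. PTPRC averaged 0.0108 FPKM over the 6 samples. Only EGFL7 of 17 endothelial markers, with a mean of 2.33 FPKM, and WT1 and KRT8 of 13 mesothelial and epithelial rows, at most 1.16 FPKM, passed the filter, and none of 17 skeletal muscle markers did (at most 0.555 FPKM). Of 13 thermogenic adipocyte markers, 4 were tested (FGF21, TMEM26, CIDEA and COX7A1) and none was called by limma or limma voom, while 1 had an unadjusted p under 0.05, with 1 lower when adjusted over the list alone (camera of limma, adjusted p = 0.352).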

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

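Some of these tests, named below, were chosen after the results were seen. No named gene or list that passed the threshold changed sign under the alternatives run, and no gene called both here and in an alternative had the opposite direction. MEOX2 stayed past the threshold in each. Of 80 other called genes followed through them, 42 lost their call without at least 1 library, 32 without a filter, 18 without the trend, 18 with the replicate block and 2 to 4 in each other setting that ended a call; apart from single libraries, ADM lost its call in 8 settings, F3 in 7, SLC2A1 in 5 and ACSL3 and TUSC5 in 4 each. The count of 350 was 324 and 337 with pseudocounts of 0.1 and 0.5, 352 after quantile normalization, 327 after rescaling to TPM, 298 without the trend, 370 with a robust fit, 337 with vooma weights and 422 with protein-coding rows alone, which was added after seeing the data. Median-of-ratios scaling gave 350 and tests nothing, because the values carry that scaling already. Without a filter, where 18740 genes were tested, it was 194 (113 higher, 81 lower; 173 shared with the 350). With limma voom on the recovered reads, chosen after seeing the data, it was 574 (309 higher, 265 lower; 327 shared), and 109 genes changed by at least 1 on the log2 scale. With a mean of at least 5 FPKM, 314 genes were called (274 shared) and 37 changed by at least 1, fewer low genes being tested; the smooth muscle and pericyte markers list (0.0225) and the TGF-beta and BMP signalling list (0.0294) then passed camera. The cause of the voom difference was not tested.

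Without single libraries the count ranged from 117 to 276, the higher genes from 69 to 154 and the lower genes from 48 to 122. The adjusted p of camera ranged from 0.0430 (stronger, without MEOX2 sample 3) to 0.352 for the adipogenic transcription factors and from 0.485 to 0.998 for the PI3K/AKT core list. The direction of that uncalled list also turned without a filter (0.728) and without MEOX2 sample 1 (0.708) or NC sample 2 (0.858). The mature adipocyte list lost its call only with an estimated correlation (0.155), among the settings run. Fry asks whether the genes of a list moved one way on balance and, unlike camera, does not compare them with other genes, so the counts of the 2 tests are not alternatives of one another. By fry 5 lists passed, the mature adipocyte list among them (0.00482), and the glycolysis and hypoxia list (0.185) and the growth factors and receptors upstream of PI3K/AKT list (0.0711) did not. No list passed 0.05 with an estimated correlation, against 7 of 21 with the preset one. Among these 7, the estimate was below the preset 0.01 for cell cycle (-0.0205) and for lipolysis and fatty acid oxidation (-0.0183). It was 0.0247 to 0.198 for the others, so the losses are not in every case a matter of correlated members. With an estimated correlation, camera also uses only the few residual degrees of freedom of 6 samples, which raises p for the same statistic. For the lists with a higher estimate, the part of each was not separated.

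The replicate block, with the replicate number as a term, gave 242 genes (135 higher, 107 lower; 224 shared). Samples with the same number had deviation correlations of -0.0747, 0.0204 and -0.00417, and samples with different numbers had -0.0854 to 0.0858. No link between samples of the same number was therefore seen, but this cannot show whether they were prepared in matched sets. Depths of 11772772 to 12230863 reads leave genes such as SNORD14, at 0 to 3 reads, without a dependable change.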

Other observations

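All tests in this part were chosen after the results were seen, and so were the genes named in the next 2 paragraphs.

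Single genes of the cytoskeleton rose with MEOX2; they were picked from the called genes and show nothing of the group as a whole. MLCK, the myosin light chain kinase, went from 51.4 to 79.2 FPKM, MYL9, a myosin regulatory light chain, from 121.7 to 162.0, PALLD, an actin-bundling protein, from 65.0 to 93.0 and DSTN, an actin-severing protein, from 370.0 to 500.8. Of 4 rows named ACTB, ENSOARG00000014814 rose by 0.92 and ENSOARG00000012108 by 0.50 on the log2 scale. The more abundant ENSOARG00000003021 (2081 against 1893 FPKM; limma adjusted p = 0.691) and ENSOARG00000018506 (2199 against 1999 FPKM; 0.488) were not called. Actin copies can share reads, so all 4 are uncertain; ENSOARG00000012108 also lost its limma call without NC sample 1 or NC sample 2 (limma adjusted p up to 0.0870). MLCK lost its limma call in 3, MYL9 in 4 and PALLD and DSTN in 5 of the 6 fits with a library left out (limma adjusted p up to 0.0733, 0.0985, 0.102 and 0.166).

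Other single genes, picked in the same way, fell. APOE, the lipid carrier, fell from 410.8 to 193.9 FPKM, IGFBP3 from 152.6 to 68.2 and IGFBP-5 from 135.8 to 84.9. ADFP, a lipid droplet coat protein, fell from 431.7 to 280.5 FPKM, PDK4, an inhibitor of pyruvate oxidation, from 7.35 to 3.51, VDUP1, a thioredoxin-binding protein, from 241.9 to 140.2 and the metallothionein MT1A from 523.5 to 245.9. APOE lost its limma call in 2 and IGFBP3 in 4 of the 6 fits with a library left out (limma adjusted p up to 0.0549 and 0.0726), and IGFBP-5, ADFP, PDK4, VDUP1 and MT1A kept theirs in all 6.

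In the comparison as a whole, 350 genes were called, and the highest count in the other splits of the 6 samples into 3 and 3 was 0. Only the real split, 1 of 10, gave as many, and 10 splits are too few for a share under 0.05.

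Of 15 mature adipocyte markers, 6 fell with MEOX2, and the list was lower by camera of limma, a call lost with an estimated correlation (adjusted p = 0.155 with an estimated correlation). The median log2 change of the list was -0.57 as deposited, -0.57 after quantile normalization and -0.58 after rescaling to TPM. That of all tested genes was -0.00273, -0.00161 and -0.00394, so the list was lower relative to other genes under each scaling. Because the deposited values were already scaled by size factors, these rescalings could hardly move the list, and they are no test of scaling as a cause. A lower share of adipocyte-like cells stays open. The median log2 fold of the members other than ADIPOQ was -0.55 (SD 0.64, n = 14) against -2.37 for ADIPOQ, but the level of each marker in the other cells of the cultures is not known, so that share and lower expression per cell cannot be told apart. A change in expression per cell brought about by MEOX2 is a candidate explanation that was not tested.

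S100A8, S100A9, S100A12, CCL20 and IL8, genes that leukocytes also express, were grouped from genes already called lower with MEOX2, S100A8 and S100A9 being chosen after their values were seen, so their median log2 fold of -1.18 (n = 5) is set by that choice and is no test of the group. A lower share of leukocytes could do this, and the tested leukocyte markers cannot decide it. The median log2 fold of the 4 tested leukocyte markers was -0.0775 (SD 0.568), from -0.76 for CD163 to 0.56 for LAPTM5, and CD14, the most abundant, was at 117.0 FPKM with MEOX2 and 105.2 FPKM in NC. That median lies above the median of the 5 genes by more than the SD, which was the criterion set first. A stricter one, tried after this outcome was known, asks the same of each marker and was missed by CD163. Neither outcome decides on a share of leukocytes. With PTPRC at 0.0108 FPKM over the 6 samples, CD14 at these levels need not come from leukocytes, and so need not fall with them. Most rows of the leukocyte list were near 0 in both groups: 16 of 20 were below the filter, and 8 had under 5 reads in every library. In NC, PTPRC averaged 0.0141 and ITGAM 0.0638 FPKM, against 149.8 for CCL20 and 116.7 for IL8. So few leukocyte reads in NC argue against a lost share of leukocytes as the source of the CCL20 and IL8 falls. A response of the stromal cells was not tested, and S100A9 lost its limma call in 4 of the 6 fits with a library left out (limma adjusted p up to 0.0640).

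Called genes often lay next to each other: 29 adjacent pairs of tested genes were called in the same direction, 15 higher and 14 lower, against a mean of 4.64 and a maximum of 14 over 10000 random placements (permutation p = 0.0001, the smallest they can give), which argues against random placement. They include, chosen after their values were seen, ENSOARG00000007573, PSMB8, TAP1 and PSMB9 on chromosome 20 (7260803 to 7296754; log2 changes 0.70, 0.86, 0.90 and 0.92), the 3 with symbols being genes of antigen processing that interferon induces, and 3 unnamed genes on chromosome 21, ENSOARG00000009847, ENSOARG00000009865 and ENSOARG00000009963 (25773003 to 25829605; -1.12, -1.84 and -1.13), the first and last of which lost their limma calls in 4 and 3 of the 6 fits with a library left out (limma adjusted p up to 0.1005 and 0.0776). Coordinates overlapped in 3.45% of the pairs, TAP1 and PSMB9 being the only such pair, which argues against overlapping coordinates as the main source. Models that lie close without overlapping were not counted, such as ENSOARG00000007573, which ends at 7272764, and PSMB8, which starts at 7273093. Split gene models, or reads running from 1 model into the next, were therefore not tested. Reads shared between paralogs, as in S100A8, S100A9 and S100A12, and control shared by neighbours were not tested. PSMB9 lost its limma call in 3 of the 6 fits with a library left out (limma adjusted p up to 0.0646).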
